A study of Mus musculus with 2 samples.

How the data were processed

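The series holds 2 arrays of mouse colon RNA on an Affymetrix expression array, on which each transcript is read by a set of short oligonucleotide probes (a probe set). Per the series design, RNA came from a piece of the distal colon, and RNA from 4 mice was pooled for each group before hybridisation. The groups were wild-type mice of the FVB inbred strain and mice carrying an IL-9 transgene, each with 1 pool on 1 array. Mice were bred under specific pathogen-free conditions, per the labels' protocols.

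The value table deposited by the authors gives 1 intensity per probe set and array, on a linear scale. The values were made with MAS5, per the submitters' processing notes, and no version is given in the sources used here. After the lowest 2% and the highest 2% of probe sets on each array were set aside, the mean intensity was 99.99 on both arrays, the pattern that global scaling to a common target leaves. Detection calls were not used here. MAS5 subtracts an estimated background and signal from mismatched probes, which makes ratios between low values unstable.

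Each array had 22690 probe sets, of which 64 were controls. Of the other 22626, the platform annotation gave exactly 1 gene symbol to 20380, several symbols to 691 and none to 1555. Gene identifiers of 20351 single-symbol probe sets were found in the RefSeq gene table of GRCm38.p6, which was used for names only and changed 0 symbols. The genome build behind the probe annotation is not given in the sources used here, so no coordinates are printed. Genes were named only from probe sets with 1 symbol, and the probe set with the highest mean intensity over the 2 arrays stood for its gene, which gave 12393 genes.

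Intensities below a floor of 19.8, the 40th percentile of all non-control probe sets over both arrays, were set to the floor. The log2 ratio of transgenic over wild type was then taken, with no further scaling. A gene was called measured when it exceeded the floor on at least 1 array, which held for 8346 genes. Where a gene was at the floor on 1 array, its ratio is a bound, written as at least N-fold. A gene was counted as higher or lower at a log2 ratio of at least 1 in size, which is 2-fold.

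With 1 array per group there is no estimate of the spread between mice or arrays, so no test was run and no p-value or standard error is given. The number of arrays limits the precision of every value. A technical yardstick came from genes with several probe sets above the floor on both arrays (2847 genes, 7096 probe sets): the pooled SD of the log2 ratio between probe sets of a gene was 0.28 and the median SD 0.18. This yardstick holds no spread between animals.

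A set of 33 gene lists of cell types and pathways was used, 5 of them as main lists (Paneth cell, goblet cell, mast cell, type 2 immune response and epithelial antimicrobial). The Paneth and antimicrobial lists were chosen with knowledge of the published account of this study, so they are not independent evidence of its direction. For lists with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean log2 intensity in 20 bins. The resulting percentile describes these 2 arrays, and medians outside the 2.5th to 97.5th percentiles are called outside the random range.

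The genes named were Il9 and its receptor, the 10 genes with the largest ratios in each direction among those above the floor on both arrays, the 5 largest bounds in each direction, and in each list up to 4 measured members with the largest ratios in size. Members below the floor on both arrays, and members marked below as chosen after their values were seen, fall outside this rule. Not all genes that the rule names are reported here. Where another probe set of a named gene went the other way, this is said. The groups, lists, floor, threshold, naming rule and the alternatives were fixed before the data were examined, except where an alternative or list is said to have been chosen later.

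The procedure was tested on simulated arrays made from the real intensities with known ratios. The simulated noise was normal, with its size set from the typical difference between these 2 arrays at like intensity. It holds no spread between further mice or pools. Of 67 genes simulated at 2-fold, 44.8% passed the 2-fold threshold, and all 67 at 4-fold and all 66 at 8-fold did. The genes simulated at 2-fold lay at the threshold itself, so their share does not measure sensitivity to larger differences. Of 8155 genes simulated with no difference, 17 passed. Random lists of 12 genes fell outside the random range in 3% of draws with no shift and in 90% with a log2 shift of 0.3.

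The alternatives were scaling by the median, quantile normalization, an intensity-dependent loess with a span of 0.3, floors at the 20th and 60th percentiles, and no floor with a pseudocount of 1.76. Further alternatives were the mean of all probe sets of a gene, leaving out probe sets that can bind several transcripts, counting probe sets with several symbols, thresholds of 1.5-fold and 3-fold, genes above the floor on both arrays only, and unmatched random lists. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.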

Results

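Gene expression was compared between pooled distal colon RNA of wild-type FVB mice and of mice that carry a transgene for interleukin-9 (IL-9), a cytokine of type 2 immunity that acts on mast cells. Each genotype was represented by 1 array of RNA pooled from 4 mice. The median intensity was 34.0 on the wild-type array and 34.2 on the transgenic array, and 60.2% and 59.8% of probe sets exceeded the floor. The ratio of 3′ to 5′ control probe intensities, a measure of RNA integrity, was 0.719 and 0.762 for Gapdh and 1.38 and 1.30 for Actb in the wild-type and transgenic pools. Log2 intensities correlated across the 7770 genes measured on both arrays with a Pearson r of 0.979, a value across genes, which are not independent replicates.

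The comparison of genotypes addresses which genes differ in the colon when IL-9 is produced from a transgene. The mucosal mast cell protease genes Mcpt2 and Mcpt1 were far higher in the transgenic pool, as were Itln1 and Pla2g2a from the Paneth cell list. B cell, MHC class II and interferon-response genes were also higher. Digestive enzymes of the exocrine pancreas were lower in the transgenic pool by the largest ratios among measured genes. With 1 pool per genotype, lower expression in the transgenic colon cannot be told apart from pancreatic tissue carried into the wild-type pool. Of 8346 measured genes, 64 were at least 2-fold higher and 51 at least 2-fold lower in the transgenic pool, while 98.6% lay within 2-fold. The middle 95% of log2 ratios ran from −0.61 to 0.70 around a median of 0.04, and list medians and gene values given below without a fold are also log2 ratios. Of the higher genes, 15 were at the floor in wild type, and of the lower genes 26 were at the floor in transgenic colon. When pancreatic genes were left out, an alternative chosen after the data were seen, 28 genes were lower. The counts also moved by more than 1.5 times with the floor, to 202 higher and 258 lower at the 20th percentile.

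**Figure D1:**
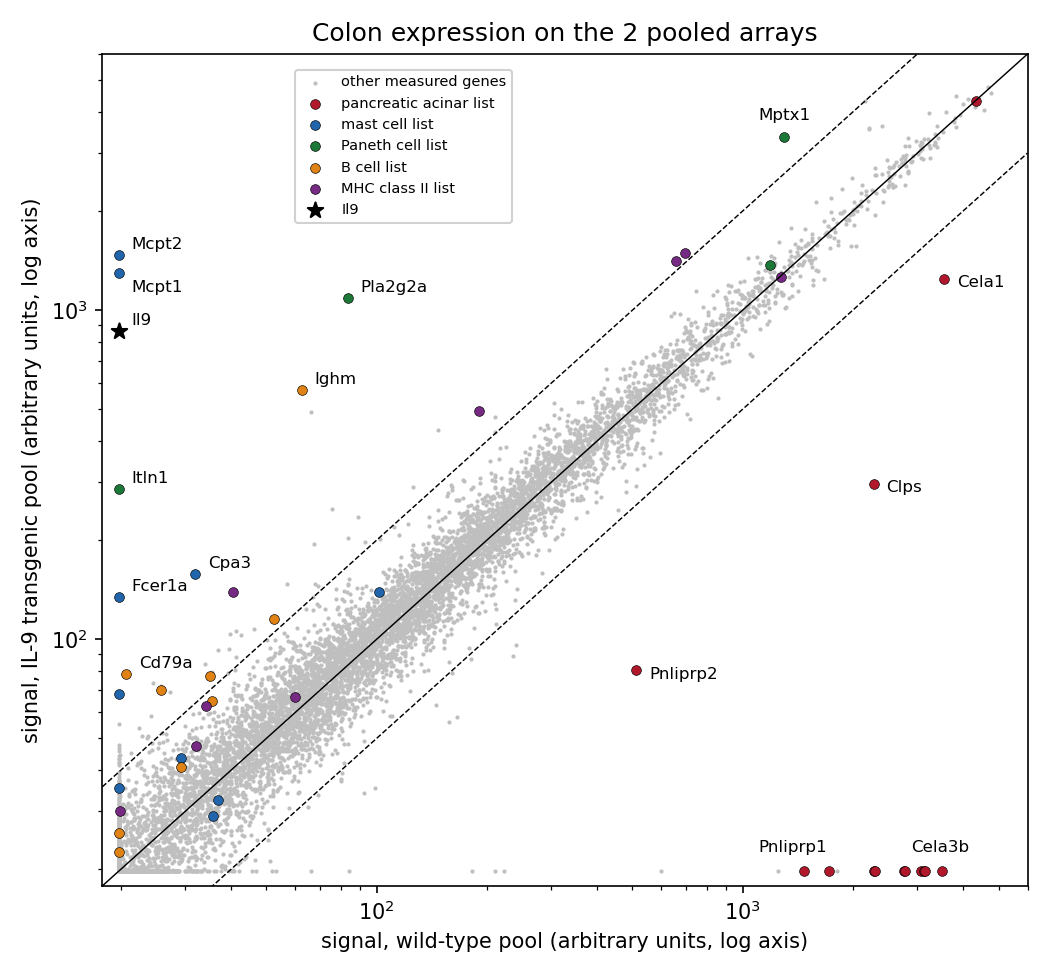
Intensity of each measured gene in the wild-type pool (x axis, arbitrary units, log scale) and the transgenic pool (y axis, arbitrary units, log scale), with intensities below the floor of 19.8 drawn at the floor. Each point is 1 gene, colours mark 5 gene lists, the solid line marks equal intensity and the dashed lines 2-fold; Mcpt1, Mcpt2 and Il9 lie on the left edge and most pancreatic enzyme genes along the lower edge.

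Il9 itself (probe set 1450565_at) had an intensity of 5.14 in wild type, below the floor, and 862 in transgenic colon, at least 43.6-fold higher. The receptor gene Il9r was below the floor on both arrays, at 4.39 and 0.488. In the list of IL-9 receptor and JAK-STAT genes, which carry the signal of this cytokine family, 0 of 13 measured members reached 2-fold, and the median log2 ratio of 0.11 lay at percentile 75.4 of matched random lists. The negative-feedback gene Socs3 had a log2 ratio of 0.83 and Bcl3, a known IL-9 target in T cells, one of 0.78, so both were less than 2-fold higher.

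Mast cell genes were higher in the transgenic pool. The chymase genes Mcpt2 (1449989_at) and Mcpt1 (1422352_at), proteases of mucosal mast cells, reached 1472 and 1297 from 14.6 and 4.96 in wild type, which is at least 74.3-fold and at least 65.5-fold. Fcer1a, the IgE-binding chain of the high-affinity IgE receptor, was at least 6.79-fold higher, and Cpa3, the mast cell carboxypeptidase, was 4.95-fold higher (32.0 to 158). The list had 10 measured members, of which 5 were at least 2-fold higher, and its median log2 ratio of 1.31 lay above every matched random list (middle 95% of random medians −0.19 to 0.27). The remaining higher member, Mcpt4, was at least 3.44-fold higher. The tryptase gene Tpsab1 and the transcription factor gene Gata2 had log2 ratios of −0.30 and −0.18. The tryptase gene Tpsb2 was at least 1.78-fold higher, and the chymase gene Cma1 and Kit had 0.58 and 0.45. All of these from Mcpt4 to Kit were chosen after their values were seen. Ms4a2, Hdc and Gata1 were below the floor on both arrays. The median was 0.94 without a floor and 4.40, over 4 members, without probe sets that can bind several transcripts.

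Within the Paneth cell list, genes of the secretory cells at the base of small intestinal crypts, 3 of 4 measured members were at least 2-fold higher; the list was chosen with knowledge of the published study and is not independent evidence of direction. Itln1 (1418165_at), an intelectin that binds microbial glycans, was below the floor in wild type at 1.86 and reached 286, at least 14.4-fold higher. Pla2g2a (1450128_at), a secreted bactericidal phospholipase, was 13.0-fold higher (83.7 to 1087), and the pentraxin gene Mptx1 was 2.60-fold higher (1295 to 3361). The lysozyme gene Lyz1 had a log2 ratio of 0.20. Mmp7, Habp2 and Defa3 were below the floor on both arrays, and 7 of the 34 genes in the list had a single-symbol probe set. The annotation gives 3 probe sets to α-defensins, the defining Paneth cell peptides, 1 of them with several symbols, and 0 exceeded the floor on either array, so the list median holds no defensin. That median was 2.54, above every matched random list; with only 4 members it moved to 1.38 with a floor at the 20th percentile and to 0.34, over 7 members, without a floor.

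Goblet cell genes, which encode mucus components and their regulators, mostly had small positive log2 ratios. Of 18 measured members 15 were positive and 1 reached 2-fold: Retnlb, which encodes the goblet cell protein RELMβ, at 2153 in wild type and 4314 in transgenic colon. Retnlb passed the threshold by a narrow margin, and its log2 ratio was 0.98 under median scaling and 0.99 under loess, below 2-fold. Capn9 had a log2 ratio of 0.86 and the goblet cell transcription factor gene Spdef 0.76, whereas Capn8, at the floor in transgenic colon, was at least 1.99-fold lower. In transgenic colon Zg16 (4330), Retnlb and Clca1 (3978) lay near the highest intensity on that array, 4753, and differences can be compressed at the top of the scale. The list median of 0.30 lay above every matched random list.

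The type 2 immune response list had 14 measured members out of 30 on the array, of which 3 were at least 2-fold higher and 1 at least 2-fold lower. The higher members were Itln1, Retnlb and the chemokine gene Ccl8, which was 2.62-fold higher, and the lower member was the trefoil peptide gene Tff2, at least 9.22-fold lower; Retnlb was below 2-fold under median scaling and loess. The cytokine genes Il4, Il5 and Il13 were below the floor on both arrays. The median of 0.36 lay at percentile 99.98, and it was 0.16 with a floor at the 20th percentile and 0.10 without a floor. Tff2 was counted with the pancreatic genes in an alternative chosen after the data were seen, in which the median was 0.41 over 13 members.

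In the epithelial antimicrobial list, 2 of 17 measured members were at least 2-fold higher (Pla2g2a and, under the main scaling but not median scaling or loess, Retnlb) and 2 at least 2-fold lower, and this list too is not independent of the study. The lower members were the regenerating-protein genes Reg1, at least 63.1-fold lower (1250 to 3.37), and Reg2, at least 3.35-fold lower, both of which are also made by the exocrine pancreas. The median was 0.20, at percentile 99.68, while the mean was −0.05, of the opposite sign. Without pancreatic genes the median was 0.31, and it was 0.078 with a floor at the 20th percentile.

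**Figure D2:**
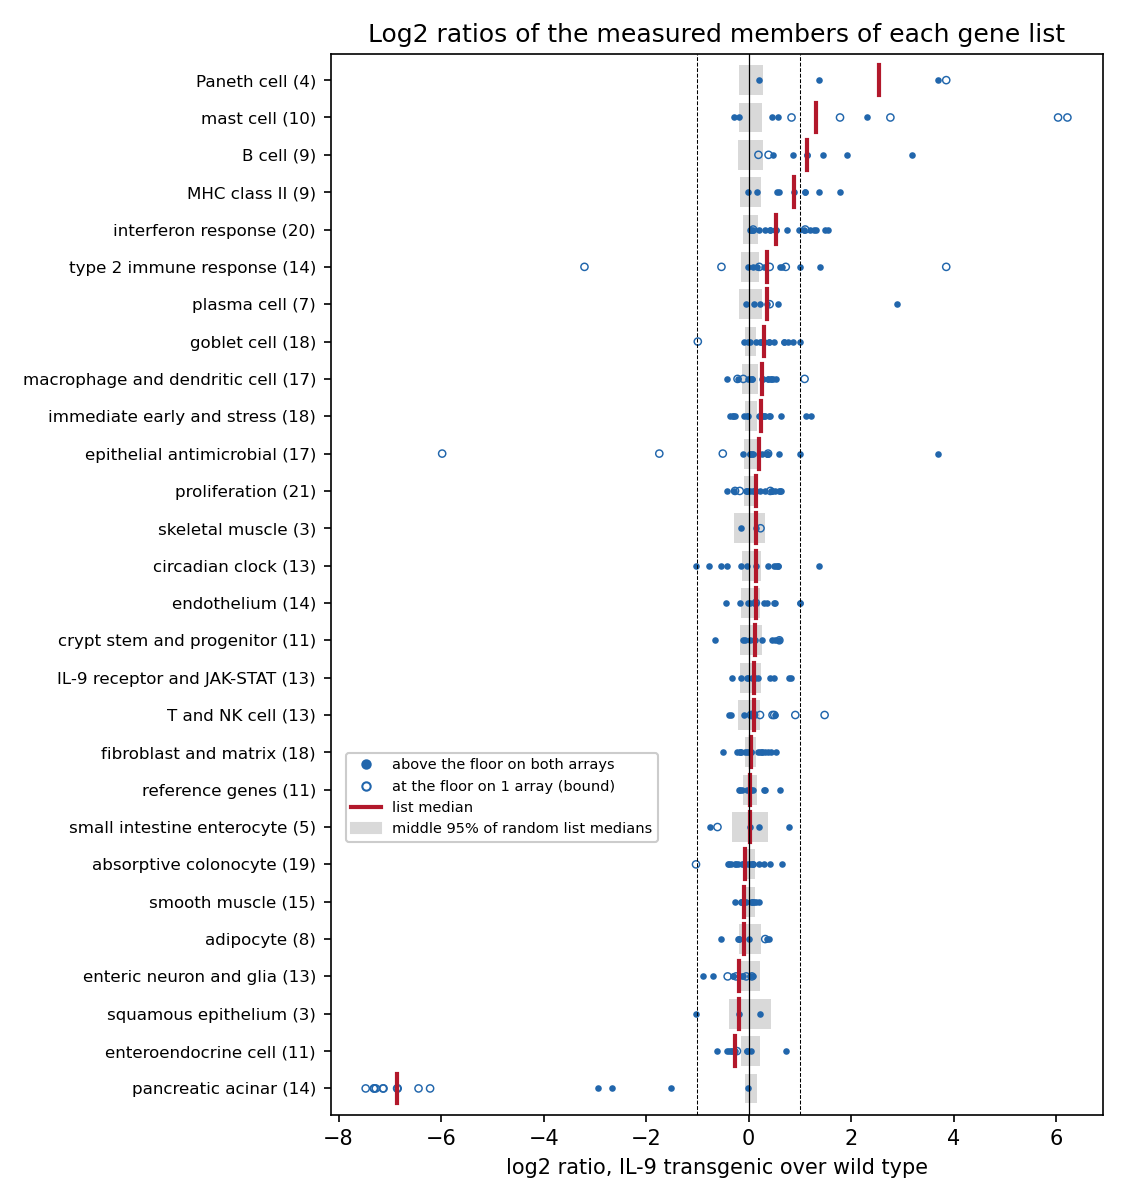
Log2 ratios of transgenic over wild type (x axis) for the measured members of each gene list with at least 3 of them (y axis, number of measured members in brackets), with filled points for genes above the floor on both arrays and open points for bounds. Red bars mark list medians, grey bands the middle 95% of medians of matched random lists and dashed lines 2-fold; the Paneth cell median of 2.54 and the pancreatic acinar median of −6.85 are the outermost.

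Genes of B cells and antigen presentation were higher in the transgenic pool. All 9 measured B cell genes had positive ratios and 5 were at least 2-fold higher. Ighm, the heavy chain of IgM, was 9.11-fold higher (62.6 to 570), with its 6 other probe sets at log2 ratios from 0.23 to 4.29. Cd79a, a signalling chain of the B cell receptor, was 3.79-fold higher, Cd22 2.72-fold and the B cell coactivator gene Pou2af1 2.21-fold; the other probe set of Cd22 had a log2 ratio of 0.06. The fifth gene, Ms4a1 (CD20), had a log2 ratio of 1.14 and was chosen after its value was seen. The list median was 1.14. Of 9 measured MHC class II genes, 4 were at least 2-fold higher, namely H2-DMa (3.43-fold), H2-Ab1 (2.59-fold), Cd74 (2.15-fold) and H2-Aa (2.14-fold), and the median was 0.88. Both medians lay above every matched random list.

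Interferon-response genes were positive in all 20 measured members, and 7 were at least 2-fold higher. Another 6 of the 26 on the array, among them Mx1, Mx2 and Cxcl10, were below the floor on both arrays. Some positive ratios were close to 0, such as those of Ifit3 (0.04) and Irf1 (0.03), both chosen after their values were seen. The guanylate-binding protein genes Gbp2 and Gbp3 were 2.92-fold and 2.80-fold higher, the GTPase gene Ifi47 2.48-fold and the immunoproteasome subunit gene Psmb9 2.43-fold. The list median of 0.53 lay above every matched random list. Without the members of the B cell, plasma cell, MHC class II and interferon lists and any immunoglobulin gene, an alternative chosen after the data were seen, 45 genes were at least 2-fold higher.

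Other immune lists differed less with the main floor. In the plasma cell list, 1 of 7 measured members reached 2-fold, the λ light chain gene Iglv1 (7.40-fold), and the median was 0.35 at percentile 99.39. Among macrophage and dendritic cell genes 1 of 17 reached 2-fold, Itgax (CD11c), at least 2.13-fold, with a median of 0.27 at percentile 99.8. Among T and NK cell genes 1 of 13 reached 2-fold, the granzyme gene Gzmb, at least 2.79-fold, and the median of 0.10 lay at percentile 82.3. That median is itself a bound, since its gene Lat was at the floor in wild type (10.2 to 21.3). Lat was chosen after its value was seen. With a floor at the 20th percentile 23 members were measured, 8 of them were at least 2-fold higher and the median was 0.77. None of 7 eosinophil genes on the array exceeded the floor, 1 of 12 neutrophil genes did (Mmp9, at least 1.59-fold lower), and 0 of 6 erythrocyte genes did.

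Pancreatic acinar genes were lower in the transgenic pool. Of 14 measured members, 13 were at least 2-fold lower and 10 of these were at the floor in transgenic colon. The elastase genes Cela3b and Cela2a had intensities of 3515 and 3148 in wild type and were at least 178-fold and at least 159-fold lower, and the chymotrypsinogen gene Ctrb1 and the trypsinogen gene Prss2 were at least 158-fold and at least 155-fold lower. The transcript 2210010C04Rik was at least 159-fold lower. Colipase (Clps), Pnliprp2 and Cela1 exceeded the floor on both arrays and were 7.69-fold, 6.37-fold and 2.85-fold lower. The exception, Zg16, was at −0.01; it also belongs to the goblet cell list and was chosen after its value was seen. The list median was −6.85, below every matched random list (middle 95% −0.07 to 0.17). The acinar list genes without Zg16 took 1.84% of the summed intensity of the wild-type array and 0.073% of that of the transgenic array. Reg1, Reg2 and Tff2, described above, were lower in the same direction.

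Epithelial and stromal lists had medians close to 0. Enteroendocrine genes were lower by a small amount, with 9 of 11 measured members negative and a median of −0.28 at percentile 0.07; the tachykinin gene Tac1 had −0.62 and the peptide hormone gene Insl5 −0.43, while Tph1, for serotonin synthesis, had 0.72. Absorptive colonocyte genes had a median of −0.08 at percentile 1.89, with 1 of 19 at least 2-fold lower, the sodium channel subunit gene Scnn1g (at least 2.04-fold), and Aqp4 at a log2 ratio of 0.64. Smooth muscle genes (15 measured) had a median of −0.08 at percentile 1.61, with Mylk at −0.27. Against unmatched random lists the colonocyte and smooth muscle medians lay at percentiles 5.49 and 6.75, inside the random range. Enteric neuron and glia genes (13 measured) had a median of −0.19 at percentile 3.39, or 0.67 against unmatched lists, and Nefl and Nos1 had −0.89 and −0.70.

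Crypt stem and progenitor genes (11 measured) had a median of 0.12 at percentile 77.7, with Slc12a2 at 0.59 and Cdca7 at −0.66. Proliferation genes (21 measured) had a median of 0.15 at percentile 95.5, with Mki67 at 0.62 and Ube2c at 0.62. Fibroblast and matrix genes (18 measured) had a median of 0.04, with Col5a1 at 0.54, although its other 2 probe sets were negative. Endothelial genes (14 measured) had a median of 0.14, with Plvap and Vwf each 2.01-fold higher, a call that both lost under median scaling (log2 ratio 0.98 each) and loess. Immediate early and stress genes, which respond within minutes of handling or stimulation, had a median of 0.23 at percentile 99.88 over 18 members, with Nr4a1 2.32-fold and Atf3 2.16-fold higher.

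Circadian clock genes (13 measured) had a median of 0.14 at percentile 81.8, and their members went both ways. Opposite signs cancel in a median, so it does not show how far single clock genes differed. The clock output gene Dbp was 2.58-fold higher and the repressor gene Nr1d1 had 0.58, while Cry1 was 2.04-fold lower and the activator gene Arntl had −0.78. Time of tissue collection is not given in the sources used here. A difference in that time between the pools was not tested and cannot be told apart from a difference by genotype.

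Lists for tissues that a colon piece can carry along held few measured genes. Adipocyte genes (8 measured) had a median of −0.09, with Car3 at −0.54. Of 19 small intestine enterocyte genes on the array 5 were measured, with Rbp2 at −0.75; the median was 0.02 and the mean −0.07, and the median was negative under each other scaling. Squamous epithelium and skeletal muscle had 3 measured genes each, with medians of −0.20 and 0.15, and Lor, a squamous envelope gene, was 2.03-fold lower. Of the tuft cell genes 2 of 7 were measured, Avil at least 1.63-fold higher and Cd24a at a log2 ratio of −0.07, with its 2 other probe sets at −0.78 and 0.03. Of the sex-linked genes Xist had an intensity of 1018 in wild type and 866 in transgenic colon, and the 3 Y-linked genes on the array were below the floor in both pools. The 11 reference genes had a median of 0.03 at percentile 53.5, with Tbp at 0.61 and B2m at 0.32.

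Further genes stood out that belong to none of the 33 lists. Icosl, the ligand of the T cell costimulator ICOS, was 2.99-fold higher, and Igkv15-103, an immunoglobulin light chain variable segment, 3.31-fold. The peptide transporter gene Slc15a1 was 2.81-fold lower, Gstm2, a glutathione transferase, 2.65-fold, the ribosomal protein gene Rps27 2.71-fold and Plxna3 2.42-fold, and the transcription factor gene Max had a log2 ratio of −1.32. Acaa1a and Cox15 were 2.86-fold and 2.80-fold lower by their brightest probe sets, but the other probe set of Acaa1a had a log2 ratio of 0.07 and the 3 others of Cox15 ranged from −0.29 to 0.13. No difference in these data has a replicate check. In simulated arrays 44.8% of differences of exactly 2-fold passed the 2-fold threshold, a share that follows largely from simulating at the threshold itself. Of 8155 genes with no difference, 17 passed. The simulated noise was set from these 2 arrays alone, so the 17 does not estimate how many of the genes named here would fail in further pools.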

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

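The tests below on other pancreatic genes, on mast cell genes that are not chymases or tryptases and on lymphoid follicle genes were chosen after the results had been seen, as was the use of quantile normalization and of the T and NK cell list to weigh an explanation; the values under that normalization, the floors and the reference and T and NK cell lists were planned. Probe sets with several gene symbols or none take no part in the gene comparison, and 1079 of them exceeded the floor on at least 1 array. At least 4-fold higher intensity in the transgenic pool, with the wild-type array as the control, drew attention to 4 of them. Probe set 1450538_s_at, whose 2 symbols both belong to the mast cell list, went from 1.51 to 993, a log2 ratio of at least 5.65. Probe sets 1426174_s_at and 1424631_a_at, with no symbol here, had log2 ratios of at least 2.33 and of 2.11, and 1451593_at, with 2 symbols, had 2.20. A further 6 such probe sets were at least 4-fold lower, among them 1416055_at, with 5 symbols, at 4440 in wild type and 4.93 in transgenic colon.

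Pancreatic enzyme genes were lower in the transgenic pool, 13 of 14 by at least 2-fold. Scaling of the arrays does not account for this: the list median was also −6.85 under quantile normalization, and reference genes had a median of 0.03. A candidate explanation is pancreatic tissue in the wild-type pool: of 10 measured genes in a separate list of other pancreatic genes, 50% were at least 2-fold lower, with Gp2 (599 to 15.6), Cuzd1 (223 to 0.683) and Pla2g1b (210 to 0.572) among them. Sycn (3244 and 3107) and Spink1 (2119 and 2406) were high in both pools, so an added pancreatic share could not be read from them. Of the 13 acinar genes other than Zg16, 3 (Clps, Pnliprp2 and Cela1) exceeded the floor in transgenic colon too, so their signal was not confined to the wild-type pool. Of the 18 genes on the array from the list of other pancreatic genes, some were below the floor in both pools. Among these were the islet gene Ins2 (11.4 and 5.34) and Ptf1a (10.4 and 4.71). Ins2 cannot decide the question, since a piece of exocrine tissue need not hold islets. With 1 pool per genotype, lower expression in the transgenic colon itself cannot be told apart from tissue carried into the wild-type pool.

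Mast cell genes were higher in the transgenic pool, with the largest ratios in the related protease genes Mcpt1 and Mcpt2. Whether probe sets of related proteases bound the same transcripts was not tested for the chymase and tryptase genes, which this explanation concerns. The 4 measured list members that are neither (Fcer1a, Cpa3, Kit and Gata2) had a median of 1.38, with 2 of them at least 2-fold higher. Higher ratios were thus not confined to chymase and tryptase probe sets. Fcer1a and Cpa3 were already known to be higher, so this median is no separate test. More mast cells in the transgenic colon may contribute, but this stays open: the 6 measured mast cell genes in none of the 33 lists had a median of 0.13 at percentile 86.0, inside the random range, with Enpp3 2.39-fold and Csf2rb2 at least 2.37-fold higher and the other 4, 3 of them bounds, at 0.09 to 0.16. Tph1, at 0.72, was left out of these 6 because it is in the enteroendocrine list. All 11 measured mast cell genes that are not chymases or tryptases had a median of 0.45 at the 100th percentile. Of these 11, 10 were positive and 4 at least 2-fold higher, but they hold Fcer1a and Cpa3, already seen to be higher. The negative ratio of Tpsab1 (−0.30) was slightly larger in size than the pooled probe set SD of 0.28, and that of Gata2 (−0.18) was smaller. The tryptase gene Tpsb2, at least 1.78-fold higher, and the chymase gene Cma1, at 0.58, went the other way. Whether the mast cells differed in type stays open and was not tested. More transcript per mast cell was not tested.

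B cell and MHC class II genes were higher in the transgenic pool. Of the 8 measured B cell genes that are not immunoglobulin genes, 8 were positive and 4 at least 2-fold higher. More lymphoid tissue in the transgenic pieces may contribute, since a lymphoid follicle list had 12 of 12 measured members positive, from Ccr6 at a log2 ratio of 0.23 and Madcam1, at least 1.26-fold higher, to Ltb at 1.08, with Ccr7 below the floor on both arrays. Its median of 0.83 lay at the 100th percentile, and without the 5 members that are general leukocyte genes the median of the other 7 was 0.74, also at the 100th percentile. The T and NK cell list, which such tissue would also bring, lay at percentile 82.3 with the main floor and at the 100th with a floor at the 20th percentile, and with 1 pool per genotype more follicles sampled by chance and an immune response to IL-9 cannot be told apart.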

How the results depend on the processing

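The results without pancreatic genes and without B cell, MHC class II and interferon genes were chosen after the data were seen; the other alternatives were planned. Of the 5 main list medians, 0 changed sign under any alternative, and 34 of 47 values moved by less than the SD of random list medians. Median scaling, quantile normalization and loess gave 59 to 64 genes higher and 50 to 52 lower, and shifted the median of all genes to 0.01 to 0.03 from 0.04. Of 940 values of named genes, 78 moved by more than the probe set SD of 0.28. Among genes at least 2-fold different in the main setting, 0 values changed sign. Sign changes of named genes with smaller ratios were not counted. Of 202 other list medians, 30 moved, and the small medians of the adipocyte, reference and small intestine enterocyte lists took both signs.

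The counts followed the floor. With a floor at the 20th percentile, 202 genes were higher and 258 lower, and the Paneth cell, type 2 and antimicrobial medians were 1.38, 0.16 and 0.078. At the 60th percentile, 29 genes were higher and 27 lower, and the Paneth cell median was 1.88. With no floor but a pseudocount, 496 were higher and 611 lower, and the Paneth cell, mast cell, type 2 and antimicrobial medians were 0.34, 0.94, 0.10 and 0.046. A lower floor admits more low intensities by construction, up to 12393 genes. With the mean of all probe sets the type 2 median was 0.50, and without probe sets that can bind several transcripts the Paneth cell and mast cell medians were 3.70 and 4.40, over 3 and 4 members. With probe sets of several symbols counted, the mast cell median was 1.78.

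At 1.5-fold, 341 genes were higher and 238 lower, and at 3-fold 13 and 21. Among genes above the floor on both arrays only, 25 were lower. Without pancreatic genes, 28 were lower, and the type 2 and antimicrobial medians were 0.41 and 0.31. The cause was not tested where the setting's construction does not give it. No paired analysis was possible because there was 1 array per group and the labels gave no replicate numbers. Low intensity over background limits the genes near the floor, and 1 pool per genotype limits every value.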

Other observations

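The lists in this part were written after the values had been seen, and their ratios are given as descriptions. Genes shared by most leukocytes were positive in 22 of 22 measured members, with a median log2 ratio of 0.54, above every matched random list. Among the 3 at least 2-fold higher were the leukocyte actin regulator gene Coro1a (1.40) and the GTPase gene Rac2 (1.17), while the common leukocyte antigen gene Ptprc had 0.80. Immunoglobulin genes were positive in 13 of 13 measured members, with a median of 0.65 and 4 of them at least 2-fold higher (Ighm, Iglv1, Igkv15-103 and Ighv14-2). Igha, the heavy chain of IgA, the main antibody of the gut, had 0.23. Its intensities of 3820 in wild type and 4476 in transgenic colon lay near the top of the scale, where differences can be compressed. MHC class I genes had a median of 0.33 at percentile 99.84, with 7 of 8 measured members positive, H2-K1 at 0.42 and H2-M3 at 0.77.

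Among genes of the secretory and metabolic machinery, 0 of 18 measured endoplasmic reticulum chaperone genes, 0 of 13 cholesterol synthesis genes and 2 of 18 drug metabolism genes differed by at least 2-fold. Endoplasmic reticulum chaperone genes had a median of 0.23 at percentile 99.92, with 12 of 18 positive, Sdf2l1 at 0.85 and Creld2 at 0.54, and with Dnajc3 at −0.44. Cholesterol synthesis genes had a median of 0.35 at percentile 99.97, with 10 of 13 positive and Mvk at 0.66. Drug metabolism genes had a median of −0.14 at percentile 0.51, with 13 of 18 negative. The 2 at least 2-fold lower were Cyp1a1, which responds to ligands of the aryl hydrocarbon receptor and was at least 2.69-fold lower, and Gstm2 at a log2 ratio of −1.41; Cyp2e1 had −0.90.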
